A study of Bos taurus with 23 samples.

How the data were processed

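Messenger RNA was sequenced from 23 explants of bovine endometrium, each cultured for 6 h, per the labels' protocols. Libraries were made with a stranded TruSeq mRNA kit. The submitters' processing notes name HISAT2, StringTie, edgeR and the genome build UMD3.1, without versions or roles, and the counting tool, the annotation release, the strand setting and any filter are not given in the sources used here. The table the authors deposited holds read counts, whole numbers that are not normalized, for 18897 genes with Ensembl identifiers, 320 of which had no read in any library. Without the counting rules, genes that overlap or have near-identical copies can share reads, and their counts are less certain.

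Group, uterus number, conceptus sex and conceptus length were taken from the titles and labels. Each of the 23 columns was matched to its sample by the column name given in the sample's description. Libraries were compared for duplication by a chi-square test of counts over genes in all 253 pairs. Its value per degree of freedom lay between 51.95 and 296.1 within groups and between 21.32 and 357.5 across groups, so no pair agreed within sampling noise and all 23 counted as separate samples.

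The gene identifiers could not be named. The reference table of gene symbols used here, for the assembly ARS-UCD2.0, matched 0 of the identifiers, and the files do not pair them with symbols. The rule for named genes was the 5 highest and 5 lowest log2 fold changes per comparison among called genes with a symbol and an average log2 CPM of at least 1, or the 3 smallest p where nothing was called, up to 4 called members of each of 20 fixed gene lists, 5 genes reported in every case, and the 8 genes in each direction that changed most clearly beyond IFNT. None of its parts could be applied, and neither could the tests of the 20 lists or the scores of lists against length. In their place the text prints 2 identifiers that rose and 2 that fell, those with the highest and lowest log2 fold change in the averaged conceptus comparison at an average log2 CPM of at least 1. They were chosen after the values were seen.

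Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 15227 genes for the groups by origin and 15099 for the groups by sex, and library sizes were scaled by TMM. The 15227 genes held 99.98% of the counts. A negative binomial model with the 4 groups was fitted to all 23 libraries and contrasts were tested with the quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Groups were Control, IFNT, AI and IVF, or Control, IFNT, Male and Female. The conceptus comparisons use the mean of the AI and IVF coefficients against Control or against IFNT. A gene counted as changed beyond IFNT when it was called against both in the same direction. Length was tested as a slope on log2 mm in the 11 conceptus libraries. These tests, the comparisons and most alternatives were chosen before the data were examined. CPM values are counts relative to the TMM-scaled library total, and log2 CPM values use a prior count of 2.

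The titles give the same numbers, written U, to explants of different groups. Deviations from the group means correlated in all 30 pairs of libraries with the same number, from r = 0.15 to 0.71 with a median of 0.51 across genes, and with a median of -0.11 between different numbers, where the highest was 0.49. Of 22 libraries with a partner, 20 were closest to a library of their own number, and the exceptions, IFNT 2 and IVF 5, were closest to each other. The numbers therefore pair the libraries, and they are called uteri here, although the labels do not spell out their meaning. The model without this block is the one fixed for the comparisons, and a model with the uterus as an additive block is printed beside it where it changed a result. The biological coefficient of variation was 36.6% without the block, with 19 residual degrees of freedom, and 23.9% with it, with 13. Without the block, the p-values rest on the spread of explants within groups, between uteri included, and treat explants of 1 uterus as independent. With the block, they rest on the spread between explants that remains after the uterus means are removed. Libraries are named by group and uterus number.

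The model was first tested on simulated data with the means, library sizes, uterus effects and dispersions of the real libraries and 200 changed genes. For IFNT vs Control, over 15227 genes, it recovered 10.4% of genes changed 1.5-fold, 47.8% of those changed 2-fold and 77.3% of those changed 4-fold without the block, and 29.9%, 68.7% and 89.4% with it. For Conceptus vs IFNT, over 15227 genes, the shares were 22.4%, 58.2% and 81.8% without and 55.2%, 82.1% and 93.9% with the block. The simulated changes were equal in AI and IVF there. Unchanged genes made up 1 of 109 calls without the block and 11 of 165 with it. For IFNT vs Control they made up 0 of 90 and 5 of 130. For Male vs Female, over 15099 genes, they were 7.46%, 44.8% and 78.8% without and 20.9%, 70.1% and 92.4% with the block.

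Likeness between comparisons that use the same Control explants was set against 20 simulated data sets without treatment effects, against independent lists, and against splits of the Control explants. The response of the IFNT-raised genes was measured in each uterus with genes called in the others by the blocked model, and tested with exact two-sided sign-flip tests over uteri. Correlations with length used 100000 permutations over 11 libraries and exact permutations within IVF, two-sided.

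Alternatives were median-ratio size factors, no filter on low counts, DESeq2 1.42.0, a model of only the groups compared, the uterus as a block, a fold minimum, terms for sex, origin or length, and each library left out in turn. The counts of genes beyond and shared with IFNT were planned for the main model only. Added after the values were seen were the held-out response of the IFNT-raised genes with its sign-flip tests, the correlation of gene group levels with length, blocked fits with other size factors, without the filter and in DESeq2, the paired levels of AI and IVF explants, all libraries of a uterus left out, counts thinned to the smallest library, the comparison of AI and of IVF with IFNT, and the calling of genes beyond IFNT without a uterus.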

Results

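The data are read counts per gene from 23 RNA libraries of bovine intercaruncular endometrium, the gland-bearing lining of the uterus between the sites of placental attachment. Explants were cut from uteri in the middle of the luteal phase and cultured for 6 h in one of 4 ways. Control explants received medium alone (n = 6). IFNT explants received recombinant ovine interferon tau at 100 ng per mL (n = 6). Interferon tau is the type I interferon that the ruminant conceptus secretes and that signals pregnancy to the mother. The remaining explants were cultured with a Day 15 conceptus, either one grown from a blastocyst produced in vivo (AI, n = 4) or one grown from a blastocyst produced in vitro (IVF, n = 7). Of the AI conceptuses 3 were female and 1 was male, and of the IVF conceptuses 2 were female and 5 were male. Conceptus length was 26.1 mm ± 4.66 (SD, n = 4) in the AI group and 25.4 mm ± 15.2 (SD, n = 7) in the IVF group. The titles of the 4 AI libraries carry 1 further code, and those of the 7 IVF libraries carry 5, of which 2 codes are each given to 2 libraries. The labels do not say what the code stands for. If it marks a shared source, the conceptuses of a code are not independent and n is smaller, above all for AI.

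Total counts per library lay between 19461678 and 36730378. They averaged 26766859 ± 4800351 (SD, n = 6) in Control, 27330146 ± 2587532 (SD, n = 6) in IFNT, 29787998 ± 1901526 (SD, n = 4) in AI and 31436122 ± 4617477 (SD, n = 7) in IVF. Between 14177 and 14682 genes had 10 or more reads in a library. The most abundant gene took between 1.08% and 2.55% of the counts, so no gene dominated a library. The first principal component held 17.0% of the variance between libraries, and uterus accounted for 83.6% of that component and treatment group for 12.1%. Treatment group accounted for 88.8% of the third component, which held 13.5% of the variance. Genes are described by groups defined from the tests, because the gene identifiers of the table could not be paired with gene symbols here.

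The first comparison asked what interferon tau alone does to the endometrium. A group of 467 genes rose and 22 fell with IFNT, and the risen genes had a median log2 fold change of 1.46. As a set, the 467 risen genes took 2.24% ± 0.0976 (SD, n = 6) of the counts in Control libraries and 8.27% ± 1.97 (SD, n = 6) in IFNT libraries. The gene with the identifier ENSBTAG00000008471 went from 1.67 CPM ± 1.38 (SD, n = 6) in Control to 874 CPM ± 661 (SD, n = 6) with IFNT, a log2 fold change of 9.05 ± 0.81 (SE, edgeR adjusted p = 2.47e-08). ENSBTAG00000009768 went from 3.59 CPM ± 1.36 (SD, n = 6) to 1460 CPM ± 498 (SD, n = 6), a log2 fold change of 8.67 ± 0.33 (SE, edgeR adjusted p = 4.5e-14). Among the fallen genes, ENSBTAG00000008735 went from 27.6 CPM ± 9.2 (SD, n = 6) to 6.5 CPM ± 2.15 (SD, n = 6), with a log2 fold change of -2.08 ± 0.29 (SE, edgeR adjusted p = 2.28e-05). Of the 489 genes called, 322 risen and 9 fallen ones changed at least 2-fold. The number of fallen genes was unstable: it was 9 without Control 1, 10 without Control 3, 13 without IFNT 2 and 11 without IFNT 4, where each number after the group is the uterus, 44 in DESeq2 and 13 in a model of only Control and IFNT. Without all libraries of uterus 1, 2, 3 or 10 it was 9 or 10.

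To measure the size of the response without choosing genes and measuring them in the same explants, IFNT-raised genes were called without one uterus at a time and their mean level was then read in that uterus. Their level with IFNT exceeded that of the Control explant of the same uterus in 6 of 6 uteri, by 1.94 ± 0.55 on the log2 scale (SD, n = 6). The exact two-sided sign-flip test gave p = 0.0312, the smallest it allows, and an adjusted p of 0.0832 over the 8 such tests. The value was 1.00 in uterus 2 and lay between 1.69 and 2.44 in the other 5, over 659 genes in uterus 2 and 388 to 460 genes in the others. With the uterus as a block, 875 genes were called, 704 higher and 171 lower, and they included 487 of the 489. Without uterus 1 this blocked count was 578, and without uterus 3 it was 543. The 171 lower genes became 101, 88 and 99 without Control 1, 3 and 5, 92 and 107 without IFNT 3 and 10, and 85, 99, 69, 105 and 103 without uterus 1, 2, 3, 4 and 10, while DESeq2 with the block called 366.

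Culture with a conceptus also raised more genes than it lowered. Against Control, 418 genes rose and 62 fell with an AI conceptus, and 445 rose and 68 fell with an IVF conceptus. The median log2 fold change of the risen genes was 1.47 with AI and 1.40 with IVF. When both kinds of conceptus were averaged, 518 genes rose and 140 fell. The numbers of fallen genes were less stable than those of risen genes. For AI the 62 became 38 without Control 1 and 38, 39, 41 and 28 without AI 1, 2, 3 and 4, and 15, 30, 32, 13 and 108 without uterus 1 to 5. For IVF the 68 became 27, 36 and 40 without Control 1, 2 and 3, 20, 21, 39 and 27 without uterus 1 to 4, and 44 in a model of only Control and IVF. For the average the 140 became 68 without Control 1, 89 without Control 2 and 91 without AI 4, and 54, 62, 65 and 222 without uterus 1, 2, 4 and 5. DESeq2 called 151, 141 and 273 fallen genes for AI, IVF and the average. ENSBTAG00000008471 reached 577 CPM ± 362 (SD, n = 4) with AI and 567 CPM ± 345 (SD, n = 7) with IVF. ENSBTAG00000009768 reached 1080 CPM ± 262 (SD, n = 4) with AI and 1130 CPM ± 188 (SD, n = 7) with IVF. Their log2 fold changes against Control, averaged over both kinds of conceptus, were 8.44 ± 0.78 (SE, edgeR adjusted p = 4.26e-08) and 8.27 ± 0.32 (SE, edgeR adjusted p = 5.21e-14). ENSBTAG00000008735 was at 5.07 CPM ± 1.27 (SD, n = 4) with AI and 7.33 CPM ± 3.11 (SD, n = 7) with IVF, a log2 fold change of -2.18 ± 0.24 (SE, edgeR adjusted p = 9.47e-07). The IFNT-raised genes took 7.76% ± 1.34 (SD, n = 4) of the counts with AI and 7.44% ± 1.18 (SD, n = 7) with IVF.

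The counts against Control were larger with the uterus as a block, at 1709 for AI, 1134 for IVF and 2068 for both kinds averaged. The block retained 479 of the 480 AI genes, 511 of the 513 IVF genes and all 658 genes of the average. In the average, risen genes went from 518 to 1248 and fallen genes from 140 to 820. The excess of risen genes was smaller in other blocked fits, with 1136 risen and 931 fallen under median-ratio size factors and 1446 and 1297 in DESeq2. Uterus 1 weighed on the counts without the block, which were 302 for AI and 431 for the average when it was left out. The blocked count for the average was 1317 without uterus 1, 1008 without uterus 3 and 1124 without uterus 4. It was 1336, 1315 and 1333 without the Control explant of uterus 1, 2 and 3 in turn, with 461, 456 and 544 fallen genes. Without uterus 1, 2, 3 and 4 the fallen genes numbered 539, 521, 447 and 361.

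**Figure D1:**
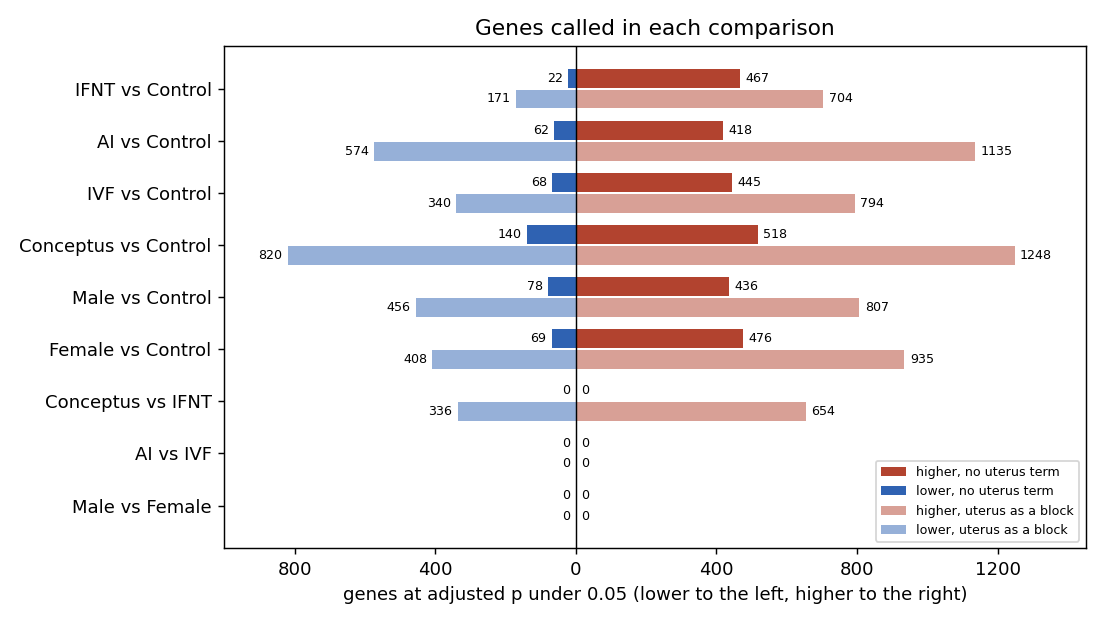
Number of genes at an adjusted p under 0.05 in each comparison (horizontal axis, genes higher to the right and lower to the left), without a term for the uterus (dark bars) and with the uterus as a block (light bars). Every comparison with Control called at least 480 genes, mostly higher, while AI vs IVF and Male vs Female called 0 in both models.

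Most genes that responded to interferon tau also responded to a conceptus. Of the 467 genes raised by IFNT, 405 were also raised by a conceptus, and of the 22 genes lowered by IFNT, 17 were also lowered. None of the tested genes was called in opposite directions. The 405 genes had a median log2 fold change of 1.59 with IFNT, 1.52 with AI and 1.52 with IVF, and a median level of 18.9 CPM in Control. The 17 genes had a median log2 fold change of -1.02 with IFNT and -0.93 with a conceptus. A further 236 genes were called against Control with a conceptus and not with IFNT, but none of them differed between conceptus and IFNT in the direct test without the block. In the held-out measure of the IFNT-raised genes, the response exceeded Control by 1.78 ± 0.40 on the log2 scale with AI (SD, n = 4, exact p = 0.125, the smallest allowed, adjusted p = 0.25) and by 1.80 ± 0.27 with IVF (SD, n = 6, exact p = 0.0312, the smallest allowed, adjusted p = 0.0832). The conceptus response differed from the IFNT response by -0.16 ± 0.31 (SD, n = 6, exact p = 0.281, adjusted p = 0.416). It was lower in 5 of 6 uteri, and uterus 2 was the exception. The conceptus response was the mean of AI and IVF in the 4 uteri that held both, and IVF alone in uteri 5 and 10.

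**Figure D2:**
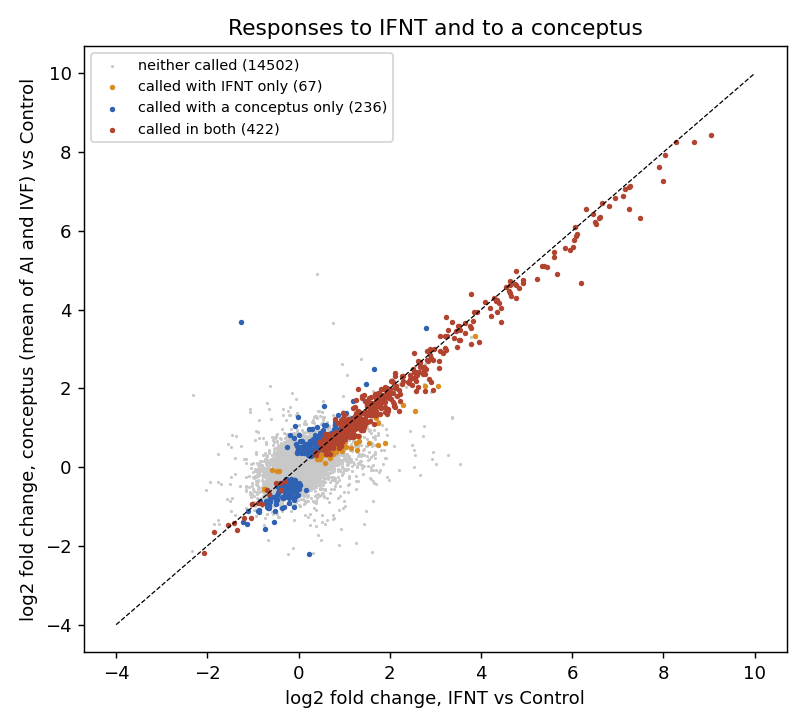
Log2 fold change against Control of each tested gene with IFNT (horizontal axis) and with a conceptus, as the mean of AI and IVF (vertical axis); the dashed line marks equal changes. The 422 genes called in both comparisons lie along that line, up to a log2 fold change of 9.05.

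**Figure D3:**
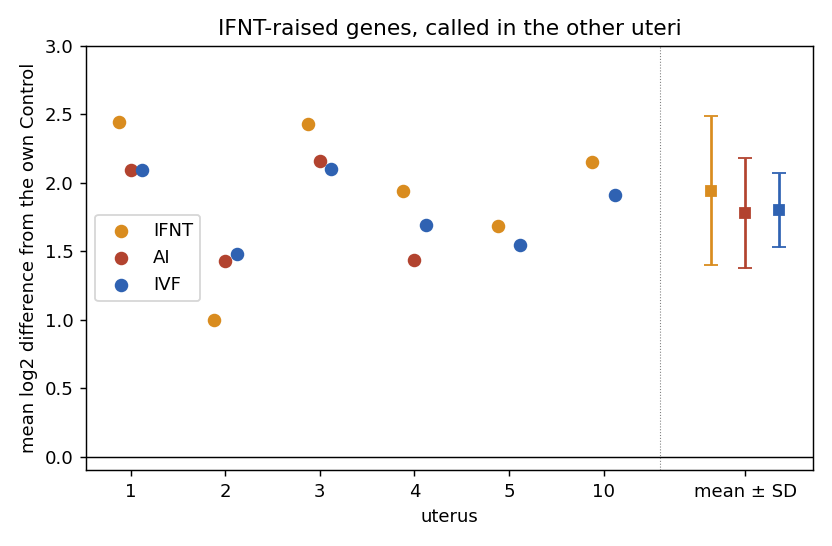
Mean log2 difference of the IFNT-raised genes from the Control explant of the same uterus (vertical axis) for each uterus (horizontal axis), with genes called in the other uteri; squares and bars on the right give the mean and SD over uteri. All points lie between 1.00 and 2.44, and the means of IFNT, AI and IVF are 1.94, 1.78 and 1.80.

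These comparisons use the same Control explants, which alone creates likeness between them. For IFNT and the averaged conceptus, lists drawn independently would share 15.9 risen and 0.202 fallen genes, where 405 and 17 were observed. The 20 simulated data sets with no treatment effect called 0 genes in each comparison, so they held no calls that could be shared and bear only on the likeness of fold changes. The log2 fold changes correlated across genes at r = 0.79, against a mean of 0.53 in the simulated sets, and genes are not independent replicates. Their covariance was 0.25 against 0.042 in the simulated sets, a difference of 0.208. When the 6 Control explants were split so that each comparison had 3 of its own, the 20 ways of doing so shared between 273 and 298 genes, and the median r was 0.45. Fewer genes were also called then, a median of 349.5 for IFNT and 406 for the conceptus, where all Control explants gave 489 and 658. The smaller number shared is therefore not a measure of lost likeness alone. AI and IVF shared 373 risen and 36 fallen genes, where independent lists would share 12.2 and 0.277. Their r was 0.75 against 0.40 in the simulated sets, their covariance 0.258 against 0.042, and with split Control explants between 255 and 274 genes were shared at a median r of 0.45. The number of shared risen and fallen genes was 354 and 10 for IFNT and AI, with covariance 0.227 against 0.043, and 380 and 12 for IFNT and IVF, with covariance 0.273 against 0.042. With split Control explants these pairs shared between 251 and 267 and between 264 and 284 genes. The median number called was then 339.5 for AI and 345.5 for IVF, where all Control explants gave 480 and 513.

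The series asked next what a conceptus does that interferon tau does not. Without the uterus in the model, edgeR called 0 genes between conceptus and IFNT, with 1524 genes at an unadjusted p under 0.05 where 761 would be expected by chance, and the smallest adjusted p was 0.163. DESeq2 called 111 genes, of which 67 were higher. With the uterus as a block, edgeR called 990 genes, 654 higher and 336 lower. Of these, 319 were also higher and 165 also lower than in Control, which makes 484 genes changed beyond IFNT by the average of AI and IVF. Taken separately with the block, AI differed from IFNT in 1058 genes and IVF in 3 by edgeR, and in 1724 and 366 by DESeq2, while the direct edgeR test of AI against IVF called 0. The 319 risen genes had a median log2 fold change against Control of 0.63 with AI, 0.35 with IVF and -0.07 with IFNT, and the 165 fallen genes had medians of -0.52, -0.34 and -0.01. Their median levels in Control were 28.7 and 27.7 CPM. A different group of 62 IFNT-raised genes was lower with a conceptus than with IFNT, at a median log2 fold change of 0.67 with IFNT and 0.17 with a conceptus. These genes and those beyond IFNT were chosen on the same explants in which their medians were read. The medians are therefore no independent measure of the size of the differences. ENSBTAG00000001021, the gene with the lowest log2 fold change against Control, belonged to the fallen genes. It was at 4.29 CPM ± 3.49 (SD, n = 6) in Control, 5.01 CPM ± 4.28 (SD, n = 6) with IFNT, 0.544 CPM ± 0.39 (SD, n = 4) with AI and 1.58 CPM ± 1.13 (SD, n = 7) with IVF. The AI libraries held only 1 to 24 reads of it, and the Control libraries 52 to 326. The IVF libraries, from 0.531 to 3.91 CPM, overlapped Control, from 1.67 to 10.3 CPM, and IFNT, from 1.34 to 12.5 CPM. Its log2 fold change with a conceptus was -2.21 ± 0.55 (SE, edgeR adjusted p = 0.019) against Control and, with the uterus as a block, -2.46 ± 0.48 (SE, edgeR adjusted p = 0.00956) against IFNT, where the model without the block gave -2.43 ± 0.56 (SE, edgeR adjusted p = 0.174). Against Control it was -2.98 ± 0.80 with AI (SE, edgeR adjusted p = 0.0387) and -1.44 ± 0.60 with IVF (SE, edgeR adjusted p = 0.318), and IVF was not called with the block either (edgeR adjusted p = 0.0829). For the averaged conceptus against Control the call was lost without the Control explant of uterus 1, at -2.03 ± 0.58 (SE, edgeR adjusted p = 0.0565). It was also lost without that of uterus 3, at -1.71 ± 0.56 (SE, edgeR adjusted p = 0.116).

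The blocked result depended on single uteri. The conceptus libraries also carry numbers apart from those of the Control and IFNT libraries, so a batch that followed these numbers could not be separated from the conceptus. Without uterus 3 or without uterus 4, edgeR called 0 genes between conceptus and IFNT and 0 beyond IFNT. Without uterus 1 the counts were 453 and 208, and without uterus 2 they were 601 and 230. The excess of higher genes was absent without uterus 2, with 304 higher and 297 lower, and without its IFNT explant alone, with 515 higher and 536 lower. Leaving out single libraries changed the 990 genes to 224 without IFNT 4, 231 without IFNT 3, 475 without IFNT 10, 414 without AI 4, 534 without AI 3, 561 without IVF 3 and 1583 without IVF 5. The 484 genes became 149 without IFNT 4, 161 without IFNT 3, 263 without IFNT 10, 210 without AI 4, 252 without AI 3, 287 without IVF 3 and 810 without IVF 5. They became 281, 251, 322 and 279 without the Control explant of uterus 1, 2, 3 and 4 in turn.

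Genes beyond IFNT were therefore also called without a uterus and read in that uterus, which was possible for uteri 1, 2, 5 and 10. The conceptus value was the mean of AI and IVF in uteri 1 and 2 and IVF alone in uteri 5 and 10. Risen genes differed between conceptus and IFNT by 0.35 in uterus 1, 0.55 in uterus 2, -0.09 in uterus 5 and 0.13 in uterus 10 on the log2 scale. Fallen genes differed by -0.31, -0.08, 0.13 and -0.27. The mean was 0.23 ± 0.28 (SD, n = 4, exact p = 0.25) for risen and -0.13 ± 0.20 (SD, n = 4, exact p = 0.375) for fallen genes, and the smallest p that 4 uteri allow is 0.125. The direction against IFNT held in 3 of 4 uteri for each set, and neither difference exceeded the spread between uteri. These means join uteri with and without an AI explant. With IVF alone in all 4 uteri, the risen genes differed from IFNT by 0.20 ± 0.25 (SD, n = 4, exact p = 0.25). The fallen genes then differed by -0.11 ± 0.19 (SD, n = 4, exact p = 0.375). With AI alone, in uteri 1 and 2, the risen genes differed from IFNT by 0.52 ± 0.14 (SD, n = 2). The fallen genes differed there by -0.24 ± 0.20 (SD, n = 2), and 2 uteri are too few for a test. Uteri 3 and 4 also held AI explants, but no gene was called without them, so the AI response could not be read there. With the conceptus value as first defined, the risen genes differed from Control by 0.22 ± 0.37 (SD, n = 4, exact p = 0.5) and were higher in 2 of 4 uteri. The fallen genes differed from Control by -0.32 ± 0.28 (SD, n = 4, exact p = 0.25) and were lower in 3 of 4.

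**Figure D4:**
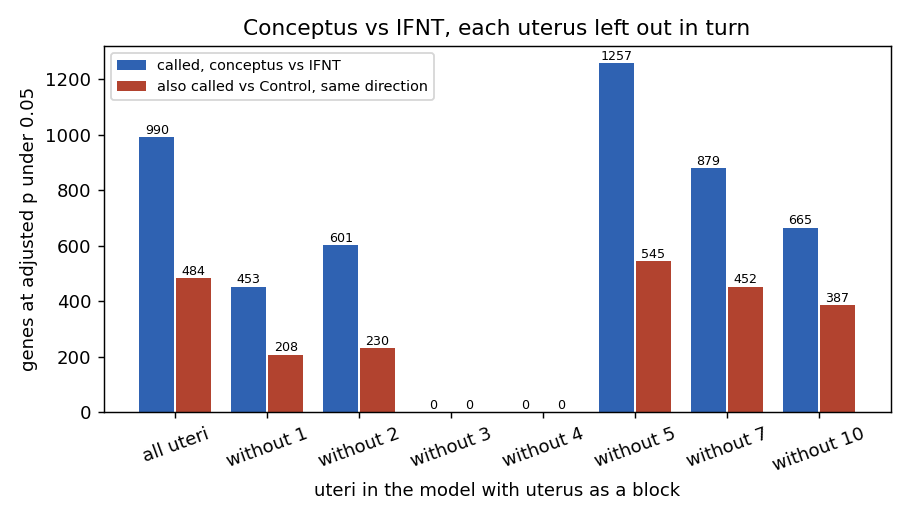
Number of genes called between conceptus and IFNT with the uterus as a block, and of those also called against Control in the same direction (vertical axis), over all uteri and without each uterus in turn (horizontal axis). The counts of 990 and 484 fall to 0 without uterus 3 and without uterus 4.

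The origin of the conceptus was tested directly. Between AI and IVF edgeR called 0 genes, with 343 at an unadjusted p under 0.05 where 761 would be expected by chance, and DESeq2 called 0. These fits ignore the uteri that AI and IVF explants share, so the shortfall is no evidence that the origins are alike. With the block edgeR again called 0, with 1254 at an unadjusted p under 0.05, and DESeq2 with the block called 85 genes, 74 higher and 11 lower in AI. The IFNT-raised genes differed between AI and IVF explants of the same uterus by -0.06 ± 0.14 on the log2 scale (SD, n = 4, exact p = 0.625, adjusted p = 0.625). Against IFNT, edgeR called 0 genes for either origin without the block, and 1058 for AI and 3 for IVF with it. DESeq2 called 24 and 8 without the block and 1724 and 366 with it. Only the direct test of AI against IVF compares the origins, and with 1 title code for all AI libraries it cannot part origin from a source that these libraries may share. On simulated counts for AI vs IVF over 15227 genes, the model without the block recovered 35.8% of genes changed 2-fold and 83.3% of genes changed 4-fold. With the block the shares were 59.7% and 89.4%. For genes changed 1.5-fold they were 8.96% without and 22.4% with it. Many differences between origins of 2-fold or less could have been missed, and some of 4-fold.

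Conceptus sex was compared in the same way. Against Control, 436 genes rose and 78 fell with a male conceptus (n = 6), and 476 rose and 69 fell with a female conceptus (n = 5). They shared 378 risen and 34 fallen genes, where independent lists would share 13.7 and 0.356. With split Control explants between 265 and 276 genes were shared, out of a median of 341.5 called for Male and 388.5 for Female. All Control explants gave 514 and 545 calls. The covariance of the fold changes was 0.232 against 0.024 in the simulated sets. The median log2 fold change of the risen genes was 1.33 with male and 1.40 with female conceptuses. The fallen genes with a male conceptus became 37, 39, 46 and 118 without Control 1, 2, 3 and 5, 46 and 48 without IVF 1 and 5, and 17, 33 and 27 without uterus 1, 2 and 4, with 38 in a model of only Control and Male. Those with a female conceptus became 36 without Control 1, 36 without AI 2 and 35 without IVF 2, and 21, 17, 37, 37 and 126 without uterus 1 to 5. DESeq2 called 170 and 189 fallen genes. The block gave 1263 and 1343 genes, and without uterus 1 the count for male conceptuses in the model without the block was 341. Between male and female conceptuses edgeR called 0 genes, with 1089 at an unadjusted p under 0.05 where 755 would be expected by chance, and DESeq2 called 0. With the block edgeR called 0, with 1757 at an unadjusted p under 0.05, and DESeq2 called 18, of which 14 were higher with male conceptuses. Sex and origin were uneven, with 3 of 4 AI and 2 of 7 IVF conceptuses female, and a term for the other factor left both direct counts at 0.

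Conceptus length ranged from 8 to 54 mm, and no gene was called for it. In the 11 conceptus libraries edgeR called 0 of 14822 genes for a slope on log2 length, with 280 at an unadjusted p under 0.05 where 741 would be expected by chance. This fit leaves out the uterus, so the shortfall is no evidence that length has no effect. The mean level of the IFNT-raised genes correlated with log2 length at r = -0.02 (permutation p = 0.953, adjusted p = 0.972) and rho = 0.105 (permutation p = 0.758, adjusted p = 0.758) over 11 libraries, with r = -0.25 after the 2 most distant lengths were left out. Within the 7 IVF libraries r was -0.18 (exact permutation p = 0.695, adjusted p = 0.767) and rho was -0.071 (exact permutation p = 0.906, adjusted p = 1). The risen and fallen genes beyond IFNT gave r = -0.013 (permutation p = 0.972, adjusted p = 0.972) and r = -0.139 (permutation p = 0.687, adjusted p = 0.972), with rho = 0.105 and -0.123 (permutation p = 0.758 and 0.72, both adjusted p = 0.758), so that 3 gene groups were examined. Without the 2 most distant lengths r was 0.463 and -0.377. These permutations ignore the uterus. In the 4 uteri that held both, the AI conceptus was the longer in 4 of 4, and its explant had the higher level of the risen genes in 4 of 4, by 0.26 ± 0.14 on the log2 scale (SD, n = 4), and the lower level of the fallen genes in 4 of 4, at a difference of -0.17 ± 0.09 (SD, n = 4). Each exact two-sided sign-flip p was 0.125, the smallest 4 uteri allow (adjusted p = 0.188 over 3 gene groups). Length and origin cannot be separated in these pairs, and the genes were chosen on the same libraries. The level of the IFNT-raised genes was higher with AI in 2 of 4 uteri, with a mean difference of -0.03 ± 0.16 (SD, n = 4, exact p = 0.875, adjusted p = 0.875). With 4 AI conceptuses, a relation within AI was not examined.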

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

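The regroupings within uteri, thinning to equal depth, the count of genes seen with a conceptus and almost not without one, the levels of the IVF 3 genes in other conceptus libraries and the treatment test of the co-varying genes were added after the data were seen, but before their own results were. The tests of library numbers, of the fallen genes in held-out uteri, of depth, spill-over and uterus for the IVF 3 genes and of uterus differences for the co-varying genes were chosen after their results were seen.

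Chance assignment of the libraries was examined by regrouping them, with 32 splits drawn for each comparison, the real one included. In the comparisons with Control only the real split, 1 of 32, gave as many genes. This share is the smallest that 32 splits allow and was not adjusted over the comparisons. It argues against an assignment by chance that ignores the uterus. These splits move libraries across uteri, and few of them part Control from treatment within as many uteri as the real one: none of the others for IFNT and the averaged conceptus, and 1 for AI, 2 for IVF, 3 for Male and 5 for Female, each with 0 genes. The real and the highest other count were 489 and 333 for IFNT, 480 and 121 for AI, 513 and 4 for IVF, 514 and 19 for Male, 545 and 0 for Female, and 658 and 67 for the averaged conceptus. For AI vs IVF, Male vs Female and Conceptus vs IFNT the real count was 0, so that 32 of 32 splits had to give as many and the splits decide nothing there. The highest other counts were 3, 0 and 0. With the uterus as a block and labels moved only within uteri, 1 of 32 regroupings gave as many genes for IFNT vs Control, 875 against at most 438, and 1 of 32 for Conceptus vs IFNT, 990 against at most 36. The same held in 1 of 32 for IVF vs Control, 1134 against at most 119 with the mirror of a split, the same model there, counted once, in 1 of 32 for Male, 1263 against at most 458, in 1 of 24 for Female, 1343 against at most 1, and in 1 of 32 for the averaged conceptus, 2068 against at most 2. Each of these shares is the smallest that its regroupings allow, and none was adjusted over the comparisons. For Conceptus vs IFNT and the averaged conceptus only part of the possible regroupings was drawn. Taken singly, the shares argue against an assignment by chance within uteri for these 6, but they do not exclude it. For AI the 16 regroupings are too few for a share under 0.05, and the real count was 1709 where the highest other was 1066. The counts of 1066 for AI and 458 for Male came from exchanging the labels in every shared uterus, which is nearly the mirror of the real split. The real split parts IFNT from Control in all 6 uteri, and the split with 333 genes did so in 4.

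The first pattern is the set of 484 genes that the average of AI and IVF changed beyond IFNT with the uterus as a block, where AI alone differed from IFNT in 1058 genes and IVF alone in 3. Unequal depth is argued against, since 384 of them passed again after all libraries were thinned to the smallest total. RNA of the conceptus itself in the explants may contribute to the 319 risen genes and is not settled: only 4 genes were seen with a conceptus and almost not without one, against 1 in the reverse direction (exact binomial p = 0.375), and genes outside the table were not examined; nor is it settled for the fallen genes, which lay at -0.32 ± 0.28 (SD, n = 4) from Control in uteri not used to call them. A library batch cannot be told apart from the conceptus, because 0 of the 11 conceptus libraries carry a number among those of the Control and IFNT libraries. Since the set was 0 without uterus 3 or 4, an effect of conceptus products other than interferon tau stays an open hypothesis.

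The second pattern is a set of 14 genes seen almost only in IVF 3, each with at least 20 reads and at least 10 times those of any other library. IVF 3 stood apart from the other IVF libraries, where the next had 3 such genes, and from the other Male libraries, where the next had 1. The 14 genes had between 27 and 598 reads in IVF 3 and 3217 in all. Depth is argued against by the deepest library, IVF 7, which had 0 such genes, while spill-over and the uterus itself were not decided. The other libraries held at most 2.33% of its reads and, within uterus 3, at most 2.69% of its level, but the choice of these genes fixed such low values. Tissue of that conceptus on the explant could be a source and was not settled: 0 of the 14 genes rose above the highest library without a conceptus in any other conceptus library, but each explant had its own conceptus, so a fragment in one well need not appear in others, and no biological explanation was tested.

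The third pattern is a set of 50 genes that rose and fell together between explants after treatment and uterus means were removed, and that held its highest levels in IFNT 2, IVF 1 and IVF 5. Their mean log2 CPM was 4.96, 4.76 and 4.50 there and as low as -1.21 in IVF 2, and their share of the counts ran from 0.0212% to 1.5%. Within a uterus their level spanned 3.59 on the log2 scale on average, and the uterus means spanned 3.28. The permutation test over treatment groups gave p = 0.555. Because the genes were chosen after removal of both kinds of means, neither value settles how much uterus or treatment contributes. A candidate explanation is a difference in the tissue that each small biopsy caught, which was not tested.

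Counting the 2 sets with IVF 3 above, a library stood far from the rest of its group in 9 of 73 sets of values. All 6 sets of counts of genes seen almost only in 1 library were among them, and a single gene among zeros suffices there. Of the other 67 sets 3 stood out, where chance gives about 1 in 20. IVF 4 had the lowest mean log2 CPM of the risen genes beyond IFNT among Female libraries, at 4.95, where the next was 5.34. The Female libraries join 3 AI and 2 IVF libraries. Among IVF libraries the next lowest was IVF 1, at 5.06, and IVF 4 did not stand out there. IVF 10 had the lowest mean of the fallen genes among IVF libraries, at 4.07, where the next was 4.32. IVF 4 had 3 genes seen almost only there, while the other Female libraries had 0. Control 5, IFNT 2 and AI 4 each had 1 such gene, where the rest of their groups had 0. ENSBTAG00000001021 was at 3.91 CPM in IVF 7, where the next IVF library was at 1.83 CPM.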

How the results depend on the processing

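The edgeR block, alone or with a term for sex or origin, was planned for the comparisons. The counts of genes beyond and shared with IFNT under the block were not planned. Blocked refits with other size factors or no filter and DESeq2 with the block were chosen after the data were seen. The same holds for thinning, the omission of a uterus and the held-out response. No call of a printed gene changed direction, and the cause was not tested unless stated. The replicate block raised the counts of called genes for IFNT vs Control to 875, AI to 1709, IVF to 1134, Male to 1263, Female to 1343, the averaged conceptus to 2068, Conceptus vs IFNT to 990, genes beyond IFNT to 484 and genes shared with IFNT from 422 to 648; it removes the spread between uteri, and it left AI vs IVF, Male vs Female and length at 0. DESeq2 without the block gave 111 for Conceptus vs IFNT and 46 beyond IFNT. DESeq2 with the replicate block gave 85 for AI vs IVF, 18 for Male vs Female, 1665 for Conceptus vs IFNT and 812 beyond IFNT. An absolute log2 fold change of at least 1 left 313 genes for IVF, 305 for Male, 340 for Female and 332 for the averaged conceptus, by construction fewer. Leaving out a library or a uterus gave 302 to 534 genes for AI vs Control, 341 to 528 for Male, 431 to 741 for the averaged conceptus, and 0 to 1 for Conceptus vs IFNT and for genes beyond IFNT, the single gene appearing without uterus 10. With the replicate block the same omissions gave 543 to 940 for IFNT vs Control, 1008 to 2411 for the averaged conceptus, 0 to 1583 for Conceptus vs IFNT and 0 to 810 beyond IFNT. IFNT vs Control stayed between 361 and 527, IVF vs Control between 373 and 511 and Female vs Control between 378 and 592 without the block. AI vs IVF, Male vs Female and length stayed at 0 in each omission, and also with median-ratio size factors, without the filter and with terms for sex, origin or length where run. When genes were called without the block, the response of the IFNT-raised genes was larger with all 3 treatments, at 2.35 with AI, 2.27 with IVF and 2.45 with IFNT on the log2 scale. The planned tests of fixed gene lists were not run. At 2-fold, 47.8% of simulated changes between IFNT and Control were recovered without the block, so many changes of 2-fold or less may have stayed uncalled. The simulation did not vary depth, so it does not show what limits the calls.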

Other observations

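The values here were examined after the data were seen. Over one list, the IFNT-raised genes of all uteri, the log2 difference from the Control explant with IFNT was 1.41 in uterus 2, where it was 1.89 with AI and 1.95 with IVF. In the other 5 uteri it lay between 1.70 and 2.32 with IFNT and between 1.48 and 1.93 with IVF. Of the 4 uteri with an AI explant, uterus 4 had the lowest AI value, at 1.53. The IFNT-raised genes took 5.24% of the counts in IFNT 2 and 10.7% in IFNT 1, while the 6 Control libraries lay between 2.11% and 2.39%. IFNT 2 was also the library with the highest level of the 50 co-varying genes, of which 0 were called for IFNT or conceptus against Control or between them, with or without the block. Because these genes were chosen for wide variation within groups and uteri, the absence of calls says little about treatment.

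The median level of the IFNT-raised genes was 17.3 CPM in Control against 15.6 CPM over all tested genes, and 10.1% of the IFNT-raised genes were under 1 CPM against 12.1% of all tested genes. Of the 319 risen genes beyond IFNT 1.57% were under 1 CPM in Control. With the uterus as a block, 5 IFNT-raised genes were higher with a conceptus than with IFNT. Their medians were 0.83 with a conceptus and 0.43 with IFNT on the log2 scale, read in the same explants that chose them.

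In AI 4, 1 gene held 5272 reads, at least 10 times its reads in any other library. In IVF 4, 3 genes of this kind held 1000 reads together.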
